A study of Mus musculus with 3 samples.

How the data were processed

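Spleen cells of Mus musculus were measured as single-cell polyA RNA in 3 libraries, 1 per group (Chow, MASH, MASH-Phe-free). Per the labels' protocols, cells in buffered saline were loaded on a Chromium Next GEM chip with a 5′ single-cell kit and libraries were sequenced in pairs on an Illumina NovaSeq system. Per the file headers, the deposited counts are whole UMI counts per gene and barcode made with Cell Ranger 9.0.1, and no barcode held fewer than 500 UMIs, so the authors' cell calling had been applied. Other deposited columns gave identifiers and symbols of 33696 genes and the cell barcodes, per the file headers and values. Per the submitters' processing notes the genome was GRCm39/mm39 and Seurat 5.3.0 was used, in a role not given in the sources used here. The annotation release was likewise not given in the sources used here, and no gene positions were reported.

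The counts were reprocessed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs, which left 15984 Chow, 17651 MASH and 15864 Phe-free barcodes. Barcodes under 300 genes numbered 240, 1235 and 602, and those above the mitochondrial limit 336, 441 and 627. Scrublet, run per library with its automatic threshold, removed 362, 336 and 329 barcodes as doublets, or 2.26%, 1.90% and 2.07%. The shares expected from the number of barcodes were 13.2%, 15.4% and 13.4%, so at those rates most doublets remained in the classes compared. A further 84, 53 and 37 cells that carried at least 4 markers of the other lymphoid class were left out as mixed. Counts were scaled to 10000 UMIs per cell and log transformed, 2000 variable genes were chosen without immunoglobulin, T-cell-receptor, haemoglobin, mitochondrial, ribosomal and sex-linked genes, and 30 principal components and 15 neighbours were used. Leiden clustering at resolution 1.0 on all libraries together, with no integration, gave 60 clusters. The B-like clusters were divided again into 15 clusters and the T-like into 14. A cluster was named by the marker list with the highest mean log2 fold of its 5 leading markers, if this was at least 1.5 with at least 3 markers higher, and left unnamed otherwise. Clusters in which another type scored at least 1.5 and at least 0.6 of the best, cycling clusters (score at least 1.5) and unnamed clusters were divided again at resolution 0.5. This was done where they held at least 60 cells. The parts were then named in the same way, and no cluster was left out as mixed. Subsets needed a mean of at least 0.5 over 3 leading markers, with a CPM offset of 5.

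Shares were given with exact Clopper-Pearson 95% intervals, and ratios of shares with 95% intervals from the binomial counts on the log scale. Expression was summed over the cells of a class in a library and given as counts per 1e6 (CPM), with ratios and exact conditional Poisson 95% intervals, and log2 ratios used an offset of 10 CPM. A library summed to between 35520959 and 48917149 UMIs in B-like cells and between 6391679 and 9072030 UMIs in plasma-like cells, which set the width of these intervals. A list was summarised by the median log2 ratio of members with at least 20 UMIs and its percentile among 10000 random lists of the same size matched on expression in 20 bins, and its interval came from 1000 Poisson redraws. The heavy chain of a cell was its highest constant gene. Shares of cells with a UMI were taken after cells were thinned to the 10th percentile of UMIs of their class, shallower cells being left out. Free RNA was estimated from marker genes of other classes. The lower quartile of their level relative to those classes was taken, which leans low. Free RNA so estimated made up 0.308%, 0.328% and 0.356% of B-like, 0.586%, 0.749% and 0.889% of plasma-like, and 0.484%, 0.513% and 0.565% of T-like UMIs. In other classes it made up 1.13%, 2.21% and 0.489% of NK-like, 4.75%, 5.32% and 1.76% of dendritic-like, 2.38%, 3.43% and 2.07% of monocyte- and macrophage-like, and 3.66%, 2.72% and 3.01% of neutrophil-like UMIs.

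The groups followed the labels, and MASH was compared with Chow and Phe-free with MASH, the Chow value being given beside. With 1 library per group no test between groups was run. Genes were named by a fixed rule: those farthest apart in each direction, 4 and 4 in B-like and plasma-like, 3 and 3 in T-like, and 2 and 2 in monocyte- and macrophage-like and in neutrophil-like cells. A named gene needed at least 50 UMIs, at least 30 CPM in the higher library, an interval that excluded 1, and at least 2% of its CPM in the class where it was highest, and the class at least 50 cells in both libraries. Immunoglobulin, T-cell-receptor, haemoglobin, mitochondrial, ribosomal, sex-linked and model genes were not eligible. At most 4 members farthest apart were eligible as examples of each list, and those cited were picked among them after their values were seen. A few genes that met these rules are not reported here. The filters, the gene lists, the markers, the rule for named genes, the comparisons and 61 alternatives were chosen before the data were examined.

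Chosen after the data were seen were 7 alternatives, 3 further gene lists, the thresholds for naming clusters, the rule for mixed cells, the free RNA estimate, the division of erythroid-like and neutrophil-like clusters by maturity, the use of heavy-chain variable segments, and which combinations of list and class were reported. Older symbols of some members of the amino acid deprivation list were added after first list values had been seen. Late erythroid-like clusters held at least 10% haemoglobin UMIs, and immature neutrophil-like clusters at least 100 CPM of each granule gene. The per-cell alternative to clusters counted plasma-like cells with at least 5 (strict: 7) of 11 markers and B-like and T-like cells with at least 3 markers.

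The alternatives were a looser filter (200 genes, no UMI minimum, 20% mitochondrial), a stricter filter (500 genes, 1000 UMIs, 5%), doublets kept, variable genes with the excluded families, resolutions of 0.5 and 2.0, each library clustered on its own, per-cell marker gates, other denominators, an offset of 1 CPM, trimmed-mean (TMM) scaling, scaling without the most abundant gene families, subtraction of free RNA, a mean over cells in place of a sum, the same weight for each cluster in both libraries (at least 20 cells each; in plasma-like and NK-like cells 1 cluster had enough, so the setting only left out the smaller cluster), no minimum of UMIs for list members, thinning to the 25th percentile and none, and an isotype that needed 80% of the heavy-chain UMIs.

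The expression steps were tested on simulated data in which both libraries of a pair were drawn by Poisson counts from their pooled class profile and 200 genes were changed. The intervals assume the same Poisson counts, so the simulation checks the steps only. It could not show the error that arises where a few cells hold most UMIs of a gene. In B-like cells, of 13375 genes for MASH against Chow, 91.0% of genes changed 1.5-fold, 95.2% of those changed 2-fold and 100% of those changed 4-fold had intervals that excluded 1, as did 5.45% of unchanged genes. In plasma-like cells, of 8471 genes, these were 71.6%, 95.2%, 100% and 4.50%. For Phe-free against MASH they were 97.0%, 95.2%, 100% and 5.29% of 13135 genes in B-like cells and 73.1%, 96.8%, 100% and 4.99% of 8819 genes in plasma-like cells. Simulated raised lists lay at the 100th percentile, and in B-like and plasma-like cells between 4 and 8 of 100 unchanged lists lay outside the central 95%. These lists held genes drawn at random with independent counts. They could not show how often a list whose members vary together in the same cells reaches an extreme percentile. The percentiles therefore only describe these libraries.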

Results

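Single-cell RNA of mouse spleen was counted in 3 libraries from 3 groups with 1 library each: Chow, MASH (metabolic dysfunction-associated steatohepatitis) and MASH with a phenylalanine-free treatment (Phe-free). The Chow library held 16495 cell barcodes with 138787602 unique molecular identifiers (UMIs), the MASH library 19219 barcodes with 152501471 UMIs, and the Phe-free library 16778 barcodes with 160115282 UMIs. The median barcode held 7169 UMIs and 2690 genes in Chow, 5873 UMIs and 2088 genes in MASH, and 6263 UMIs and 2377 genes in Phe-free. After filtering, 15538 Chow, 17262 MASH and 15498 Phe-free cells were compared. There were no replicates in any group, so no difference between groups was tested and no spread between animals was known. The sample labels give the tissue and the group. The diets, the number of animals per library and whether these mice bore tumours were not given for the spleens in the sources used here, while the series text describes mice with implanted liver tumours and RNA of tumour tissue. The 95% intervals in brackets cover counting error only, and those of expression ratios treat UMIs as independent and leave out differences between cells. Class names such as B-like stand for clusters of cells that resemble a type by its marker genes. Clusters that matched no type held 3.04% of Chow, 6.30% of MASH and 3.32% of Phe-free cells.

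The first question was how the makeup of the spleen differed between MASH and Chow. Erythroid-like cells, the red cell precursors, were 0.708% of Chow cells and 5.65% of MASH cells, a ratio of 7.98 [6.56–9.71]. Late erythroid-like clusters, led by haemoglobin and the red cell membrane gene Slc4a1, held 10 Chow and 530 MASH cells, a ratio of shares of 47.7 [25.5–89.2]. Early erythroid-like clusters, led by Car1 and Klf1, held 100 Chow and 445 MASH cells, a ratio of 4.01 [3.23–4.97]. Immature neutrophil-like clusters, led by the granule genes Camp, Ltf and Ngp, made up 3.30% of Chow and 0.597% of MASH cells, a ratio of 0.181 [0.146–0.223]. The mature neutrophil-like cluster, led by Il1b, Cxcr2 and Csf3r, made up 3.92% of Chow and 4.63% of MASH cells, a ratio of 1.18 [1.07–1.31]. Shares were also lower in MASH for B-like cells, at 29.0% against 35.5%, a ratio of 0.817 [0.791–0.843], and for T-like cells, at 16.7% against 20.9%, a ratio of 0.80 [0.764–0.837]. Macrophage-like cells were 16.1% in Chow and 19.2% in MASH (ratio 1.19 [1.14–1.25]), and dendritic-like cells were 5.69% and 7.65% (1.34 [1.24–1.46]). The macrophage-like cells were shallow, with a median of 1046, 1076 and 1158 UMIs in Chow, MASH and Phe-free. NK-like cells were 3.09% and 3.35% (1.08 [0.962–1.22]), and monocyte-like cells were 4.58% and 3.96% (0.866 [0.781–0.960]). Stroma-like cells were 36 in Chow and 66 in MASH, a ratio of shares of 1.65 [1.10–2.48]. Eosinophil-like cells were 11 and 34, a ratio of 2.78 [1.41–5.49]. The haemoglobin gene Hbb-bs also had a UMI in 0.876% of Chow, 14.1% of MASH and 4.56% of Phe-free T-like cells thinned to 1117 UMIs, against 42.4%, 84.9% and 56.7% of erythroid-like cells. Without thinning these were 5.05%, 54.8% and 17.8% of T-like cells and 60.0%, 93.9% and 75.8% of erythroid-like cells, at median depths of 8949, 9020 and 8227 UMIs and of 12176, 6906 and 14614 UMIs. With each library clustered on its own, the log2 ratio of shares was 1.63 in place of 3.0 for erythroid-like, −0.07 in place of −0.21 for monocyte-like and 0.15 in place of 0.25 for macrophage-like cells, which had 0.54 with the stricter filter. The log2 ratio for B-like cells was −0.12 at resolution 0.5 in place of −0.29.

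**Figure D1:**
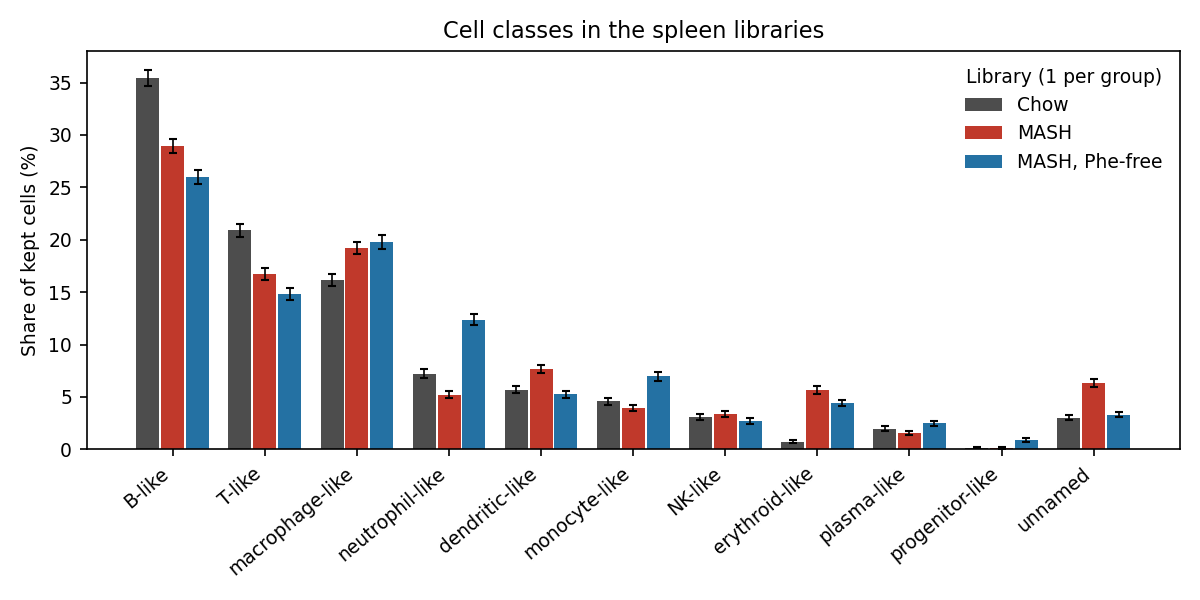
Share of kept cells (%, vertical axis) in each cell class, with 1 bar per library and exact binomial 95% intervals as error bars. Neutrophil-like cells were 7.22% of Chow, 5.23% of MASH and 12.3% of Phe-free cells, and B-like cells 35.5%, 29.0% and 26.0%.

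The next question was what went with the phenylalanine-free treatment in MASH. Neutrophil-like cells were 5.23% of MASH and 12.3% of Phe-free cells, a ratio of 2.36 [2.19–2.55], and the immature clusters held 103 MASH and 908 Phe-free cells, a ratio of shares of 9.82 [8.02–12.0]. The mature neutrophil-like cluster held 800 and 1005 cells, a ratio of 1.40 [1.28–1.53]. Monocyte-like cells were 3.96% of MASH and 6.96% of Phe-free cells, a ratio of 1.76 [1.60–1.93]. Progenitor-like cells numbered 22 in MASH and 137 in Phe-free, a ratio of shares of 6.94 [4.42–10.9], against 26 in Chow. Erythroid-like cells were 5.65% in MASH and 4.41% in Phe-free (ratio 0.780 [0.709–0.858]), which was 6.23 [5.10–7.60] times the Chow share. The late clusters held 530 MASH and 66 Phe-free cells, a ratio of shares of 0.139 [0.108–0.179], while the early clusters held 617 cells, a ratio of 1.54 [1.37–1.74]. Shares were lower in Phe-free for B-like cells (26.0%, ratio 0.897 [0.866–0.929]), T-like cells (14.8%, 0.887 [0.843–0.933]), NK-like cells (2.70%, 0.807 [0.713–0.914]) and dendritic-like cells (5.24%, 0.685 [0.630–0.746]). Macrophage-like cells were 19.8% in Phe-free, a ratio of 1.03 [0.985–1.08] to MASH. Eosinophil-like cells were 34 in MASH and 11 in Phe-free (0.360 [0.183–0.711]), and stroma-like cells 66 and 30 (0.506 [0.329–0.779]). With each library clustered on its own, the log2 ratio was 1.86 in place of 2.79 for progenitor-like cells and −0.55 in place of 0.04 for macrophage-like cells. Without erythroid-like and neutrophil-like cells in the total it was −0.06 in place of −0.16 for B-like and −0.08 in place of −0.17 for T-like cells, and with the stricter filter −0.18 in place of −0.36 for erythroid-like cells.

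**Figure D2:**
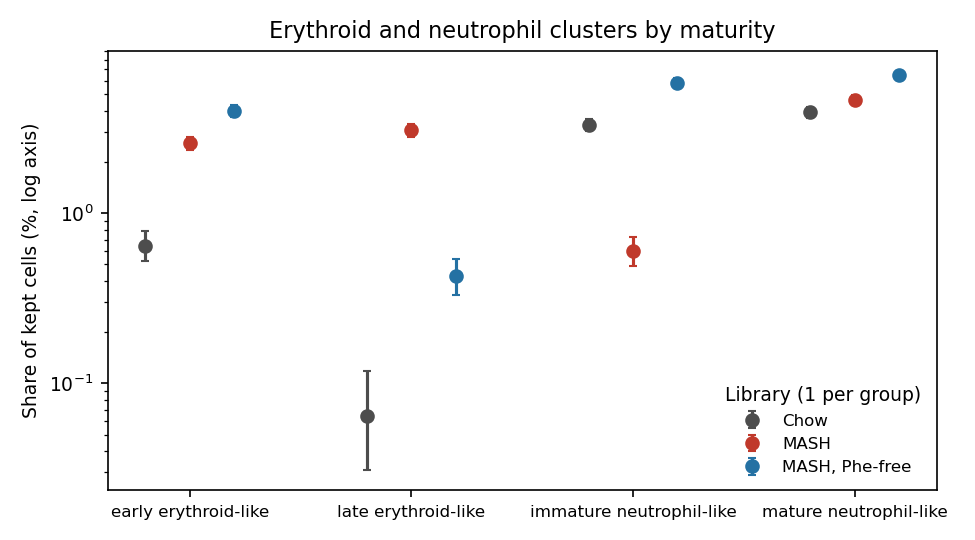
Share of kept cells (%, vertical log axis) in the early and late erythroid-like and the immature and mature neutrophil-like clusters, with 1 point per library and exact binomial 95% intervals. Late erythroid-like cells were 0.0644% of Chow, 3.07% of MASH and 0.426% of Phe-free cells, and immature neutrophil-like cells 3.30%, 0.597% and 5.86%.

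Plasma cell differentiation is named in the series title, and plasma-like cells were compared as a share of all cells and of the B lineage. They were 1.98% [1.77–2.21] of Chow, 1.52% [1.34–1.71] of MASH and 2.48% [2.24–2.73] of Phe-free cells, from 308, 262 and 384 cells. The ratio was 0.766 [0.650–0.902] for MASH over Chow, 1.63 [1.40–1.91] for Phe-free over MASH and 1.25 [1.08–1.45] for Phe-free over Chow. Of the B lineage they were 5.29% [4.73–5.90] in Chow, 4.98% [4.41–5.60] in MASH and 8.71% [7.89–9.58] in Phe-free. Within the B lineage the ratio was 0.941 [0.801–1.10] for MASH over Chow and 1.75 [1.5–2.04] for Phe-free over MASH. The antibody joining chain Jchain (ENSMUSG00000067149) had a UMI in 100%, 98.7% and 99.2% of plasma-like cells thinned to 2349 UMIs, with 39, 30 and 27 shallower cells left out, and in 2.85%, 2.07% and 3.13% of T-like cells. Without thinning these were 99.7%, 99.6% and 99.5% of plasma-like cells and 8.44%, 5.62% and 7.88% of T-like cells, at median depths of 16245, 19294 and 17354 UMIs and of 8949, 9020 and 8227 UMIs. When plasma-like cells were instead taken one by one as cells with at least 5 of 11 plasma markers, the log2 ratio of Phe-free over MASH was 0.17 in place of 0.71. That gate held 2155 cells, of which 1009 lay in B-like clusters, so many cells lay near its limit.

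The heavy chain most abundant in a plasma-like cell was IgM (Ighm) in 289 of 308 Chow cells (93.8% [90.5–96.2]), 249 of 262 MASH cells (95% [91.7–97.3]) and 341 of 384 Phe-free cells (88.8% [85.2–91.8]). The ratio of Ighm shares was 0.934 [0.893–0.977] for Phe-free over MASH. IgA (Igha) led in 15 Chow, 5 MASH and 26 Phe-free cells, or 4.87%, 1.91% and 6.77%, a ratio of 0.392 [0.144–1.06] for MASH over Chow and 3.55 [1.38–9.12] for Phe-free over MASH. Ighg1 led in 2, 1 and 7 cells, Ighg2b in 0, 2 and 3, Ighg2c in 2, 3 and 5, Ighg3 in 0, 2 and 0, and Ighe in 0, 0 and 2. Among T-like cells with any heavy-chain UMI, given as a background, Ighm led in 97.498%, 98.2% and 97.2% and Igha in 0.245%, 0.225% and 0.608%. Free RNA was not set apart from other sources there: 1 MASH T-like cell held 2914 of the 2920 Igha UMIs. Summed over plasma-like cells, Ighm stood at 53107, 47135 and 39176 counts per 1e6 (CPM) and Igha at 3117, 1024 and 1878 CPM.

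B-like subsets were compared as shares of the 5818 Chow, 5262 MASH and 4411 Phe-free B-lineage cells. Germinal centre-like cells, in which antibody genes mutate and switch, were 0.928% of Chow, 1.12% of MASH and 1.81% of Phe-free B-lineage cells, from 54, 59 and 80 cells. The ratio was 1.21 [0.837–1.74] for MASH over Chow, 1.62 [1.16–2.26] for Phe-free over MASH and 1.95 [1.39–2.75] for Phe-free over Chow. Transitional-like cells were 6.84%, 10.6% and 8.41%, with ratios of 1.56 [1.38–1.76] and 0.790 [0.697–0.896], and 21, 13 and 37 of them lay in a cluster led by B cell precursor genes such as Igll1. Follicular-like cells were 34.2%, 31.8% and 27.1%, with ratios of 0.929 [0.880–0.979] and 0.852 [0.80–0.907]. Marginal zone markers named 4 clusters, but 1 of them, with 234, 158 and 105 cells, had haemoglobin genes and no marginal zone marker among its leading genes, so their joint share was not compared. Of the others, with Asb2, Ackr3 or Cd9 among their leading genes, 1 held 864, 377 and 278 cells, another 349, 802 and 754, and the last 213, 159 and 206. The clusters with 864 and 349 Chow cells shared leading genes such as Asb2, Ackr3 and Ffar2, so their counts were not read as changes of separate subsets. B1-like cells were 5.60%, 6.27% and 6.14%, and B-like cells of no subset were 18.6%, 16.8% and 17.4%. These include 67, 103 and 91 cells of a shallow cluster, with a median of 1312 UMIs, whose leading genes include markers of plasmacytoid dendritic cells and which stayed in the B-like class and its totals. No cluster matched age-associated B cells, which sets no limit on such cells within other clusters. With each library clustered on its own, the log2 ratio of Phe-free over MASH turned from 0.69 to −0.82 for germinal centre-like cells and from −0.23 to 0.09 for follicular-like cells, and was −0.13 in place of −0.34 for transitional-like cells. With per-cell marker gates, the log2 ratio of MASH over Chow was 0.13 in place of 0.64 for transitional-like and −0.37 in place of 0.27 for germinal centre-like cells.

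Among T-like cells, CD4-like cells were 39.5% in Chow, 34.2% in MASH and 31.8% in Phe-free, and CD8-like cells 36.7%, 41.7% and 39.8%. The ratio for MASH over Chow was 0.866 [0.811–0.926] for CD4-like and 1.14 [1.07–1.21] for CD8-like cells. Regulatory T-like cells, which restrain immune responses, were 14.2%, 13.7% and 16.7%, a ratio of 1.21 [1.07–1.38] for Phe-free over MASH. The gamma-delta markers named a pair of clusters, but only 1 of them, with 33, 15 and 31 cells, was led by gamma-delta receptor genes, and the other held 36, 40 and 62 cells, so their joint share was not compared. Follicular helper-like cells, which help B cells in germinal centres, were 3.11%, 4.20% and 3.57%, a ratio of 1.35 [1.04–1.75] for MASH over Chow and 0.851 for Phe-free over MASH. T-like cells of no subset were 4.41%, 4.26% and 4.14%. With each library clustered on its own, the log2 ratio of MASH over Chow turned from −0.21 to 0.22 for CD4-like and from 0.43 to −1.57 for follicular helper-like cells, and it was 0.04 in place of 0.19 for CD8-like cells with per-cell marker gates. The follicular helper-like ratio of Phe-free over MASH was −0.11 at resolution 0.5 in place of −0.23.

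Gene expression was first compared between MASH and Chow for the type I interferon response list, whose genes are switched on by antiviral interferons. In B-like cells 26 of 26 measured members were higher in MASH, all 26 with intervals above 1, and the median log2 ratio of 0.54 lay at the 100th percentile of random lists. Ifi27l2a (ENSMUSG00000079017) was 2.80 [2.73–2.88] times higher at 167 and 469 CPM, Ifi44 (ENSMUSG00000028037) 3.30 [3.0–3.65] times, Ifit3 (ENSMUSG00000074896) 2.96 [2.70–3.26] times and Rtp4 2.70 [2.48–2.95] times. The median was 0.48 in T-like cells with 26 of 26 members higher, 0.49 in plasma-like cells with 15 of 15 higher, and 0.42 in NK-like cells with 22 of 24 higher. It was 0.76 in dendritic-like cells with 25 of 26 higher, 0.80 in monocyte- and macrophage-like cells with 26 of 26 higher, and 2.01 in neutrophil-like cells with 24 of 25 higher. All these medians lay at the 100th percentile. The ubiquitin-like modifier Isg15 (ENSMUSG00000035692) was 7.53 [7.20–7.89] times higher in neutrophil-like cells, at 189 and 1420 CPM, 3.03 [2.83–3.25] times in monocyte- and macrophage-like cells, 2.73 [2.37–3.16] times in dendritic-like cells, 2.12 [1.98–2.27] times in T-like cells and 5.31 [3.66–7.91] times in plasma-like cells. Ifi27l2a was 4.20 [3.41–5.21] times higher in NK-like cells and 2.44 [2.28–2.62] times in plasma-like cells. When B-like clusters were weighted alike in both libraries the B-like median was 0.13, with Ifi44 at 0.16, Rtp4 at 0.23 and Ifit3 at −0.35, and the neutrophil-like median was 0.78 with Isg15 at 1.45 in place of 2.85, while the medians were 0.48 in T-like, 0.76 in dendritic-like and 0.82 in monocyte- and macrophage-like cells. With no minimum of UMIs for list members the plasma-like median was 0.25.

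In Phe-free over MASH the type I interferon response list went the other way in the same classes. In B-like cells 25 of 26 members were lower, 24 with intervals below 1, and the median was −0.42 at percentile 0. Ifi44 was at 0.291 [0.260–0.326] times its MASH level with 11.1, 36.7 and 10.7 CPM in Chow, MASH and Phe-free, Irf7 at 0.487 [0.447–0.530] times with 17.7, 43.3 and 21.1 CPM, and Oasl1 at 0.459 [0.413–0.509] times. The median was −0.27 in T-like cells with 26 of 26 members lower, −0.33 in plasma-like cells with 13 of 18 lower, −0.37 in NK-like cells with 21 of 24 lower, −0.69 in dendritic-like cells with 24 of 26 lower, −0.50 in monocyte- and macrophage-like cells with 26 of 26 lower, and −1.95 in neutrophil-like cells with 24 of 24 lower, all at percentile 0. Isg15 was at 0.347 [0.303–0.396] times in dendritic-like cells. In monocyte- and macrophage-like cells Ifi44 was at 0.565 [0.543–0.588] and Oasl1 at 0.373 [0.311–0.445] times. In T-like cells Ifit1 was at 0.657 [0.584–0.738] and the related interferon-inducible gene Mndal at 0.739 [0.717–0.762] times. In NK-like cells Ifi27l2a was at 0.493 [0.418–0.578] times. Weighting clusters alike gave a neutrophil-like median of −0.77 and Irf7 at −0.31 in place of −0.78 in B-like cells, and with no minimum of UMIs for list members the plasma-like median was −0.0710.

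**Figure D3:**
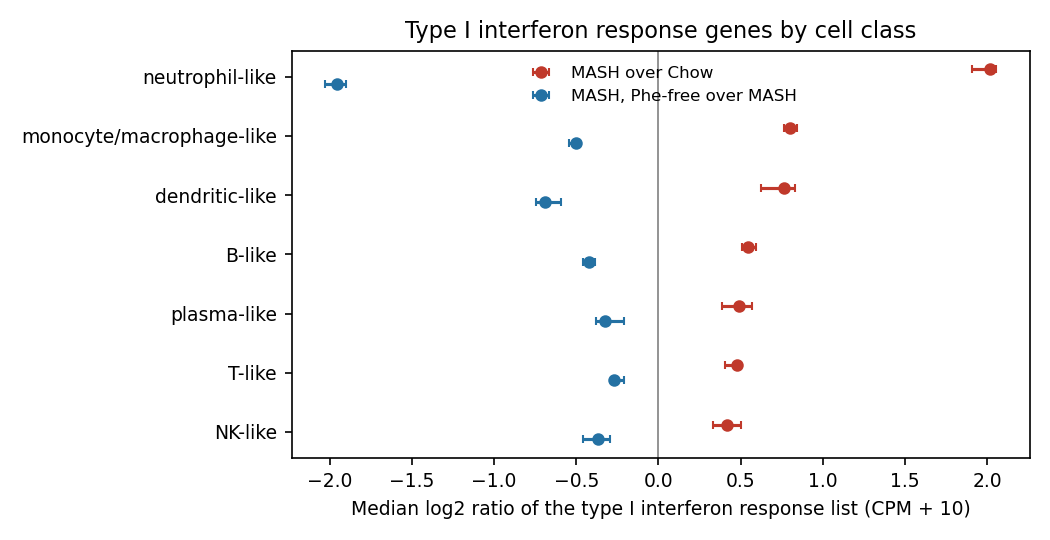
Median log2 ratio of the type I interferon response list (horizontal axis, CPM + 10) in 7 cell classes, with red points for MASH over Chow, blue points for Phe-free over MASH, and 95% intervals from Poisson redraws of the counts. The red medians ran from 0.42 in NK-like to 2.01 in neutrophil-like cells and the blue medians from −1.95 in neutrophil-like to −0.27 in T-like cells.

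Outside the type I interferon response list, B-like cells of MASH were compared with those of Chow for the genes farthest apart. Whether these genes answered to interferon was not tested. The surface antigen Ly6a (ENSMUSG00000075602) was 4.41 [4.23–4.60] times higher, at 55.4 CPM in Chow, 244 in MASH and 123 in Phe-free. The glucocorticoid-induced chaperone Fkbp5 (ENSMUSG00000024222) stood at 190, 37.6 and 39.1 CPM, a ratio of 0.199 [0.189–0.209] for MASH over Chow. Pik3ip1, an inhibitor of phosphoinositide 3-kinase, was at 0.369 [0.351–0.387] and the protease inhibitor Serpine2 at 0.338 [0.315–0.362] times. The pancreatic enzyme gene Ctrb1 was at 0.0216 [0.0146–0.0307] times, with 30.9, 0.666 and 1.89 CPM. It had a UMI in 4.16%, 0.156% and 0.329% of B-like cells and in 3.04%, 0.0762% and 0% of T-like cells thinned to 4327 UMIs, with 559, 514 and 380 B-like cells left out. Without thinning these were 5.84%, 0.20% and 0.348% of B-like cells and 4.38%, 0.104% and 0.0436% of T-like cells, at median depths of 8226, 8483 and 7893 UMIs and of 8949, 9020 and 8227 UMIs. All 11 members of the germinal centre list were higher in MASH, 9 with intervals above 1, and the median of 0.29 lay at the 100th percentile. The neuronal-type membrane protein gene Basp1 (ENSMUSG00000045763) was 2.36 [2.03–2.75] and the signalling regulator Rgs13 1.91 [1.70–2.14] times higher. All 22 cell cycle genes were higher with a median of 0.24, with the ubiquitin-conjugating enzyme gene Ube2c at 2.78 [2.38–3.25] and the proliferation marker Mki67 (ENSMUSG00000031004) at 1.79 [1.66–1.93] times. The oxidative phosphorylation (nuclear) list was higher in 20 of 23 members with a median of 0.14, Ndufa1 at 1.18 [1.13–1.24] and Cox5a at 1.17 [1.14–1.21] times. The interferon-gamma response list was higher in 17 of 20 members with a median of 0.14 and Ifi47 at 1.31 [1.25–1.37] times. These 3 medians lay at the 100th percentile. Equal cluster weights gave a germinal centre median of 0.03 and an interferon-gamma median of −0.000741, with Rgs13 at −0.00841 in place of 0.53, Ifi47 at −0.0405 in place of 0.34, Ndufa1 at 0.12 and Cox5a at 0.11, both in place of 0.22. Averaging over cells gave a cell cycle median of 0.05, with Ube2c at 0.32 in place of 0.64 and Mki67 at 0.27 in place of 0.63, and Basp1 was at 0.23 in place of 0.54.

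The plasma cell differentiation list, which leads from B cells to antibody secretion, had a median of 0.02 in B-like cells for MASH over Chow, with 9 of 17 members higher, at percentile 84.0. For Phe-free over MASH it was 0.05 with 11 of 16 members higher, at percentile 99.7. The secretion cofactor Mzb1 was 1.11 [1.09–1.13] times higher in Phe-free. Jchain was 1.32 [1.22–1.42] times higher, at 24.2, 30.4 and 40.1 CPM, but stood at 24.2, 19.9 and 28.1 CPM in T-like cells, so free RNA was not set apart from the B-like level, and its log2 ratio was 0.06 in place of 0.31 under equal cluster weights. The lymphoid organisation and tertiary lymphoid structure list had a median of −0.02 with 6 of 15 members higher for MASH over Chow, and of 0.06 with 8 of 14 higher for Phe-free over MASH, at percentiles 19.6 and 99.97. The aromatic amino acid metabolism and transport list, which holds the enzymes and carriers of phenylalanine, had medians of −0.04 with 4 of 12 measured members higher and −0.01 with 5 of 12 higher, at percentiles 20 and 48.3. The secreted phenylalanine oxidase Il4i1 stood at 55.5 CPM in Chow, 71.1 in MASH and 80 in Phe-free, with ratios of 1.28 [1.22–1.35] and 1.13 [1.07–1.18]. The carrier subunit Slc3a2 was at 0.900 [0.853–0.950] times in MASH over Chow, and the biopterin synthesis enzyme Gch1 at 0.852 [0.804–0.904] times in Phe-free over MASH. The amino acid deprivation (ATF4) response list had medians of −0.00 with 11 of 24 members higher and −0.01 with 11 of 24 higher, at percentiles 76.9 and 60.6. Its member farthest apart, the stress-induced growth inhibitor Ddit4, was at 0.472 [0.455–0.490] times in MASH over Chow. Equal cluster weights gave log2 ratios of 0.13 in place of 0.31 for Il4i1 in MASH over Chow and −0.0227 in place of −0.20 for Gch1 in Phe-free over MASH.

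B-like cells of Phe-free were then compared with those of MASH. Igll1 (ENSMUSG00000075370), the surrogate light chain of B cell precursors, was 6.39 [5.54–7.39] times higher, at 5.64, 4.98 and 31.8 CPM in Chow, MASH and Phe-free, and 55.2% of its Phe-free UMIs lay in 10 cells. It had a UMI in 0.162%, 0.112% and 0.740% of B-like cells thinned to 4327 UMIs (0.163%, 0.160% and 0.720% without thinning) and in 0% of T-like cells, with 0%, 0.0347% and 0% without thinning. All 22 cell cycle genes were higher, with a median of 0.31 at the 100th percentile. Top2a was 1.66 [1.56–1.76], Mki67 1.58 [1.49–1.68] and Ube2c 2.07 [1.87–2.30] times higher. The germinal centre list was higher in 10 of 11 members, with a median of 0.25 at the 100th percentile and Basp1 at 1.60 [1.43–1.79] times. The lipoprotein gene Apoe was 1.98 [1.87–2.10] times higher, with 47.6% of its UMIs in 10 cells. The interferon-gamma response list, with 14 of 20 members higher, had a median of 0.03, and its regulator Irf1 was 1.24 [1.20–1.28] times higher. Ly6a was at 0.504 [0.486–0.522] and Ifit3 at 0.402 [0.364–0.445] times. Under equal cluster weights the medians turned to −0.14 for the cell cycle and −0.06 for the germinal centre list, and the log2 ratios were −0.18 for Top2a, −0.32 for Mki67, 0.14 for Ube2c and 0.05 for Igll1. Basp1 was at 0.19 in place of 0.41 as a mean over cells, and Apoe at 0.31 in place of 0.84 with the stricter cell filter.

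Plasma-like cells were compared by the same lists, and for MASH over Chow the median of all 8471 genes lay at −0.10, or −0.01 with trimmed-mean scaling. The protease inhibitor Slpi (ENSMUSG00000017002) was 16.5 [15.1–18.2] times higher in MASH, at 70.3 CPM in Chow, 1163 in MASH and 691 in Phe-free, but 96.7% of its MASH UMIs lay in 10 cells. It had a UMI in 7.81%, 10.3% and 12.6% of plasma-like cells thinned to 2349 UMIs and in 1.03%, 0.909% and 1.01% of T-like cells, or 15.9%, 18.7% and 23.4% and 3.27%, 2.70% and 2.87% without thinning. Ly6a was 3.28 [3.10–3.47] and Ly6k 3.68 [2.96–4.60] times higher. Lower were Zfp36l2, an RNA decay factor, at 0.266 [0.234–0.302] times, Crip1 at 0.281 [0.251–0.314] and the linker histone H1f5 at 0.188 [0.140–0.25]. The cell cycle list was lower in 20 of 21 members with a median of −0.48, Ube2c at 0.215 [0.157–0.291], Top2a at 0.305 [0.231–0.397] and Cdc20 at 0.228 [0.146–0.346] times. Of the Chow UMIs, 10 cells held 100% for Ube2c, 96.6% for H1f5, 87.5% for Crip1 and 22.0% for Zfp36l2. Of the MASH UMIs, 10 cells held 72.7% for Ly6k and 24.3% for Ly6a. The plasma cell differentiation list had a median of −0.00 with 8 of 18 members higher, at percentile 95.3, and its members went both ways. The regulator Prdm1 (ENSMUSG00000038151) was at 0.641 [0.576–0.711] times and Irf4 at 0.762 [0.711–0.817], while the surface proteoglycan Sdc1 (ENSMUSG00000020592) was at 1.43 [1.28–1.59] times. The unfolded protein response list had a median of 0.00 with 10 of 20 members higher, and its member Herpud1 was at 0.529 [0.503–0.557] times. Bst2, an interferon target, was at 1.91 [1.67–2.18] times. As a mean over cells, the cell cycle median was −0.01, Top2a turned to 0.22, Ube2c was −0.28 in place of −1.40, Cdc20 −0.26 in place of −1.02 and Slpi 2.63 in place of 3.87. Irf4 was at −0.23 in place of −0.38 with trimmed-mean scaling. H1f5 turned from −1.61 to 0.13 without the 6 Chow and 3 MASH cells of the smaller plasma-like cluster.

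In Phe-free over MASH plasma-like cells, the amino acid deprivation (ATF4) response list was higher in 18 of 24 members, 13 with intervals above 1 and 3 below, with a median of 0.23 at the 100th percentile. The serine and glycine pathway genes Shmt2 (ENSMUSG00000025403), Psph and Psat1 were 1.86 [1.59–2.17], 2.07 [1.58–2.73] and 2.09 [1.54–2.86] times higher, and the glycyl-tRNA synthetase Gars 1.62 [1.35–1.957] times. Shmt2 stood at 37.3, 35 and 65.0 CPM in Chow, MASH and Phe-free. For MASH over Chow the same list had a median of −0.04 with 9 of 24 members higher. The aromatic amino acid metabolism and transport list had medians of 0.01 for MASH over Chow and −0.02 for Phe-free over MASH. Slc7a5 (ENSMUSG00000040010), the carrier of large neutral amino acids, was at 1.40 [1.20–1.62] times in Phe-free over MASH, and its partner Slc3a2 at 0.887 [0.846–0.931]. The cell cycle list was higher in 21 of 21 members, with a median of 0.60, Ube2c at 5.47 [4.09–7.45], Top2a at 2.64 [2.04–3.47], Cdc20 at 5.76 [3.88–8.86] and the replication factor Pclaf at 5.12 [3.73–7.19] times. The 10 cells with most Ube2c held 94.1% of its Phe-free UMIs. H1f5 was 6.30 [4.80–8.42] and Crip1 3.13 [2.81–3.50] times higher, with 87.3% and 74.4% of the UMIs in 10 cells. Ly6k was at 0.303 [0.251–0.365], Ly6a at 0.498 [0.477–0.520], Ifi27l2a at 0.489 [0.462–0.518] and Apoe at 0.370 [0.289–0.470] times. Of the MASH UMIs, 10 cells held 90.59% for Apoe, 72.7% for Ly6k, 45.15% for Ifi27l2a and 24.31% for Ly6a, and for Pclaf 10 cells held 87.81% of the Phe-free UMIs. The plasma cell differentiation list had a median of 0.00 with 10 of 18 higher. The survival receptor Tnfrsf17 was at 1.21 [1.08–1.35] and the costimulator Cd28 at 0.706 [0.611–0.816] times. The unfolded protein response median was 0.04 with 14 of 20 higher, and −0.04 with trimmed-mean scaling. The neutrophil gene S100a9 was 9.81 [6.53–15.4] times higher and its log2 ratio was 0.00 in place of 1.80 once free RNA was subtracted. As a mean over cells, the cell cycle median was −0.09, H1f5 0.69, Ube2c 0.34, Top2a 0.19, Pclaf 0.17, Gars 0.14, Cdc20 0.12 and Slc3a2 −0.10. Apoe turned to 1.65 with a stricter cell filter.

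T-like cells of MASH and Chow were compared next. The chemokine Ccl5 (ENSMUSG00000035042) was 2.64 [2.61–2.68] times higher in MASH, at 844, 2233 and 1991 CPM in Chow, MASH and Phe-free. It had a UMI in 12.9%, 20.7% and 20.7% of T-like cells thinned to 4426 UMIs and in 0.871%, 1.03% and 0.524% of B-like cells, or 14.8%, 23.5% and 22.6% and 1.54%, 1.94% and 1.22% without thinning. The cytotoxic effector list was higher in 13 of 14 members with a median of 0.55, with Ccl4 at 2.64 [2.33–3.0] and the protease Gzmb at 2.0 [1.86–2.16] times. The T cell exhaustion list was higher in 9 of 11 members with a median of 0.26, with the regulator Eomes at 1.74 [1.59–1.90] and the inhibitory receptor Pdcd1 at 1.53 [1.42–1.64] times. Both medians lay at the 100th percentile. The chemokine receptor Cxcr6 was 2.15 [2.02–2.28] times higher. The naive T list was lower in 7 of 10 members with a median of −0.08, and the survival receptor Il7r was at 0.582 [0.573–0.593] times. Trnp1 was at 0.235 [0.207–0.266], Fkbp5 at 0.428 [0.405–0.452] and Klhl6 at 0.514 [0.496–0.532] times. The follicular helper list had a median of 0.06 with 8 of 12 higher, and the regulatory T list 0.04 with 7 of 10 higher. With clusters weighted alike, the log2 ratio of Ccl5 was 0.22 in place of 1.39, of Eomes 0.17, and of Pdcd1 0.13. The medians were then 0.29 for the cytotoxic effector, 0.05 for the T cell exhaustion and −0.10 for the follicular helper list.

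For Phe-free over MASH in T-like cells, the regulatory T list was higher in 8 of 10 members with a median of 0.18 at the 100th percentile. The lineage regulator Foxp3 was at 1.31 [1.23–1.39] times with 87.3, 77.9 and 102 CPM, and Tnfrsf4 at 1.36 [1.29–1.44] times. The cytotoxic effector median was −0.06 with 4 of 14 higher at percentile 2.53. Its member Gzma was at 1.73 [1.53–1.95] and Klrg1 at 0.727 [0.643–0.820] times. The T cell exhaustion, naive T and follicular helper medians were 0.03, 0.01 and −0.01, at percentiles 79.5, 54.5 and 39.6. The enkephalin precursor Penk was 2.01 [1.81–2.24] times higher, with 94.7% of its UMIs in 10 cells, and the cytokine inhibitor Socs2 was 1.58 [1.41–1.77] times higher. Resf1 was at 1.35 [1.30–1.40] and Sugct at 0.727 [0.690–0.766] times. The aromatic amino acid metabolism and transport list had medians of −0.00 and 0.03 for the 2 comparisons. With clusters weighted alike, the regulatory T median was −0.02, Foxp3 was at 0.01 and Tnfrsf4 at 0.25 in place of 0.40. As a mean over cells, Penk was at 0.15 in place of 0.75.

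Monocyte- and macrophage-like cells of MASH were likewise compared with those of Chow. Monocyte-like cells gave most UMIs of the summed classes, at 11469884, 12532805 and 16987330 in Chow, MASH and Phe-free, against 4639097, 6040552 and 6048295 from macrophage-like cells. By number of cells they were fewer, at 711, 684 and 1078 against 2506, 3318 and 3066. The acute-phase gene Saa3 (ENSMUSG00000040026) was 3.32 [3.12–3.54] times higher in MASH, at 80.2, 267 and 67.6 CPM, with 86.1% of its MASH UMIs in 10 cells, and Lrg1 was 10.8 [8.31–14.3] times higher, with 65.9% in 10 cells. Saa3 had a UMI in 3.81%, 9.62% and 8.03% of monocyte-like cells thinned to 6268 UMIs and in 0%, 0.0429% and 0% of T-like cells, or 4.78%, 14.3% and 10.6% and 0.0308%, 0.104% and 0% without thinning, at median monocyte-like depths of 15773, 17939 and 15489 UMIs. Fkbp5 was at 0.139 [0.128–0.15] times, and Ctrb1 at 0.00366 [0.000996–0.00941] times with 58.8, 0.215 and 2.17 CPM. Lgals9, a galectin, was at 2.0 [1.89–2.13] and the arginine-degrading enzyme Arg1 (ENSMUSG00000019987) at 0.257 [0.229–0.288] times, within a TGF-beta, IL-10 and immunosuppressive list whose median was −0.06. The lipid-associated macrophage list, which marks cells that take up lipid, was lower in 12 of 13 members of monocyte-like cells with a median of −0.90, and higher in 8 of 10 members of macrophage-like cells with a median of 0.20. Summed over both classes, Spp1 was at 0.142 [0.117–0.171] and the protease Ctsl at 0.467 [0.443–0.491] times. With a stricter cell filter these medians were −0.00 and −0.61. The iron handling and erythrophagocytosis list, with which macrophages recycle red cells, was higher in 6 of 9 members of macrophage-like cells with a median of 0.16 at percentile 95.6. Summed over both classes, the red pulp macrophage regulator Spic was at 1.43 [1.38–1.48] and the haem-degrading enzyme Hmox1 at 1.35 [1.32–1.37] times. With no minimum of UMIs the iron handling and erythrophagocytosis median was 0.0213, and under equal cluster weights Hmox1 was at 0.24 in place of 0.43. As a mean over cells, Saa3 was at 0.93 in place of 1.62, Lrg1 at 0.46 in place of 1.87, Arg1 at −0.83 in place of −1.57, Ctsl at 0.03 in place of −1.04 and Spp1 at −0.47 in place of −1.80.

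For Phe-free over MASH, Arg1 was 6.48 [5.83–7.21] times higher in monocyte- and macrophage-like cells, at 82.7, 21.3 and 138 CPM in Chow, MASH and Phe-free, with 92.5% of its UMIs in 10 cells. It had a UMI in 1.91%, 0.481% and 2.16% of thinned monocyte-like cells and in 0.0768%, 0% and 0.241% of T-like cells, or 1.97%, 0.877% and 2.60% and 0.154%, 0% and 0.348% without thinning. Saa3 was at 0.254 [0.240–0.269], Lrg1 at 0.345 [0.302–0.394] and Lgals9 at 0.763 [0.728–0.80] times, and the histone H2ac8 at 2.82 [2.64–3.01]. The lipid-associated macrophage list was higher in 11 of 12 members of monocyte-like cells with a median of 0.32 and in 6 of 10 of macrophage-like cells with a median of 0.04. Apoe was at 1.63 [1.58–1.68] and Cd9 at 1.61 [1.48–1.76] times in the summed classes. The iron handling and erythrophagocytosis list was higher in 8 of 9 members with a median of 0.18 at percentile 99.4 in macrophage-like cells, and the haemoglobin scavenger receptor Cd163 was at 1.83 [1.74–1.93] times in the summed classes. As a mean over cells, the lipid-associated macrophage median of monocyte-like cells was 0.16, Arg1 was at 1.49 in place of 2.24, Lgals9 at −0.21 in place of −0.37, Saa3 at −0.53 in place of −1.83, Lrg1 at −0.09 in place of −1.07 and H2ac8 at 0.40 in place of 1.36, and H2ac8 was at 0.13 under equal cluster weights. The iron handling and erythrophagocytosis median was 0.0434 with the stricter cell filter.

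Neutrophil-like cells were drawn mostly from the mature cluster in MASH and from mature and immature clusters alike in Chow and Phe-free, and the median of all genes lay at −0.11 for MASH over Chow, or −0.08 with trimmed-mean scaling, and at 0.06 or 0.11 for Phe-free over MASH. The itaconate-producing enzyme Acod1 (ENSMUSG00000022126) was 13.7 [12.2–15.4] times higher in MASH than in Chow, at 26.1, 356 and 34.3 CPM, and 0.0962 [0.0883–0.105] times its MASH level in Phe-free. It had a UMI in 10.2%, 37.8% and 10.7% of neutrophil-like cells thinned to 2884 UMIs and in 0% of T-like cells, or 12.7%, 43.3% and 13.3% and 0.0616%, 0.0347% and 0.0436% without thinning, at median depths of 5212, 4334 and 5263 UMIs. Ifit3 was 10.5 [9.77–11.4] times higher in MASH and 0.0987 [0.0929–0.105] times its MASH level in Phe-free. The myeloid suppressor and neutrophil activation list had medians of 1.10 with 10 of 14 members higher and −0.98 with 10 of 14 lower. Ifitm1 was at 6.05 [5.80–6.32] and 0.174 [0.167–0.180] times, and the cytokine Il1b at 3.49 [3.41–3.57] and 0.282 [0.277–0.288] times. The cell cycle list was lower in 22 of 22 members for MASH over Chow with a median of −0.67, and higher in 22 of 22 for Phe-free over MASH with a median of 0.88. Mki67 was at 0.466 [0.430–0.505] and 2.24 [2.07–2.42] times. Cldn1 and Tmem45a2 were at 0.180 [0.145–0.221] and 0.227 [0.191–0.268] times for MASH over Chow, and the histones H1f4 and H2ac8 at 3.96 [3.69–4.26] and 3.71 [3.38–4.08] times for Phe-free over MASH. With clusters weighted alike, Acod1 was at 2.04 and −1.63, Ifit3 at 1.73 and −1.58, Ifitm1 at 1.01 and −0.89, and Il1b at 0.17 and −0.09 on the log2 scale, and Mki67 turned to 0.63 and −0.29. Cldn1 was then at −1.15 in place of −1.97 and Tmem45a2 at −1.0 in place of −1.80 for MASH over Chow, and H1f4 at 0.49 and H2ac8 at 0.16 for Phe-free over MASH. The medians of the myeloid suppressor and neutrophil activation list were then 0.21 and −0.0591, and those of the cell cycle list turned to 0.55 and −0.17.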

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

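The tests without the B-like cluster led by interferon genes, of the cluster mix in classes other than B-like cells, of handling stress, of free haemoglobin, of red cell lysis and of glucocorticoid targets were chosen only after the result was seen. The tests of free RNA, of the cluster mix in B-like cells and of the time of day were chosen before it, and free haemoglobin and glucocorticoid targets were first recorded among these in error, with no threshold changed since.

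Some lists stood out because their medians lay on opposite sides of 0 in different classes by at least 0.2, and the difference between classes was not tested in any of them. For MASH over Chow the cell cycle list had a median of 0.84 in NK-like cells, where 22 of 22 members were higher, and −0.81 in monocyte-like cells, where 22 of 22 were lower. In NK-like cells Ube2c was 9.74 [6.79–14.4] and Mki67 2.93 [2.57–3.35] times higher, with Mki67 at 75.6, 222 and 282 CPM. Averaged over cells, the NK-like median was 0.34 and Ube2c was at 1.51 in place of 2.32 on the log2 scale, and under equal cluster weights the monocyte-like median was −0.32. Germinal centre genes were also higher in NK-like cells of MASH, with Mybl1 at 1.84, 9.19 and 5.33 CPM and Rgs13 at 0.262, 4.89 and 0 CPM, so doublets with B-like cells were not set apart. The myeloid suppressor and neutrophil activation list had a median of 0.28 in dendritic-like cells, with 6 of 11 members higher, and −0.35 in plasma-like cells, with 4 of 6 lower. Both were 0.00 once free RNA was subtracted, and the dendritic-like median turned to −0.0170 with no minimum of UMIs. For Phe-free over MASH the immunoglobulin constant genes list had a median of 0.24 in macrophage-like cells, with 7 of 8 members higher, and −0.61 in dendritic-like cells, with 7 of 7 lower and Igkc at 0.0680 [0.0540–0.0846] times. The dendritic-like median was −0.00 after free RNA was subtracted, and as a mean over cells the macrophage-like median was 0.0747 and the log2 ratio of Igkc −0.79 in place of −3.16. Neutrophil-like and erythroid-like cells were left out of this search because their clusters differed between libraries.

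Barcodes that failed the filter, which no comparison used, stood out by their haemoglobin. Haemoglobin genes held 9.31% of the UMIs of the 511 failing Chow barcodes, 65.0% of the 1568 failing MASH barcodes and 20.9% of the 914 failing Phe-free barcodes. Barcodes in which haemoglobin made up most UMIs numbered 37, 866 and 144.

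Type I interferon response genes were higher in the MASH library in 7 classes, and 3 technical accounts were weighed against a response of the animals to MASH. Free RNA of neutrophils and monocytes left the B-like median at 0.54 once subtracted. The estimate, a lower quartile, took only 0.328% from the MASH B-like UMIs. Such a subtraction could hardly move the median and does not decide on free RNA. The immediate early and dissociation list had a median of 0.0227 over 6 classes, which argues against handling stress as the whole cause. A larger share of a few interferon-responding clusters was also weighed. It is argued against in T-, dendritic- and monocyte- and macrophage-like cells, where the lowest median with clusters weighted alike was 0.48. In B-like cells that median was 0.13, as this account needs. In B-like cells that weighting gives 1 in 14 of the weight to a cluster of 121 cells (24 Chow, 71 MASH, 26 Phe-free) led by Ifit3b, Ifit3 and Ifi44, and without its cells the median was 0.53; within clusters it was higher in 12 of 14, from −0.44 to 0.68 with a median of 0.35. The rise within 12 of 14 clusters argues against a shift in clusters as the whole account in B-like cells. Such a shift stays open as a part of it. The NK- and plasma-like cells had only 1 cluster each with enough cells and the neutrophil-like 2. With 1 library per group an effect of MASH was not tested.

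Erythroid-like cells were more frequent in the MASH library, and free haemoglobin RNA and incomplete red cell lysis were weighed. Cells with at least 3 of 7 erythroid markers other than haemoglobin numbered 97 in Chow and 940 in MASH, a ratio of shares of 8.72, which argues against free haemoglobin RNA. Early erythroid-like cells, which are nucleated precursors, differed by 4.01 times, which argues against lysis for that part. Late erythroid-like cells differed by 47.7 times, as less complete lysis would give, so lysis stays open for them. More red cell formation in the MASH group may account for the early part and was not tested.

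Fkbp5 was lower in the MASH and Phe-free libraries than in Chow, at 0.199 and 0.206 times in B-like cells. Lower glucocorticoid signalling than in the Chow group may account for it: the other glucocorticoid targets had a median of −0.13 in B-like cells at percentile 0 of random lists, with 11 of 13 lower, although their median was 0.07 in neutrophil-like cells. Tsc22d3 was at 0.666 [0.650–0.683] times. Another time of day at collection was predicted to move a clock gene by over 1 in B-like cells, and the farthest, Nr1d2, was at −0.38. That limit was a choice, and a small shift in time need not reach it. The clock list had a median of −0.10 in B-like cells at percentile 0.67, with 10 of 12 lower. It was −0.24 in monocyte- and macrophage-like cells at percentile 0.01, with 11 of 12 lower, but lay at percentiles 32.3 and 31.5 in NK-like and neutrophil-like cells. The time of day therefore stays open. A lasting effect of MASH and a difference in stress at collection were not separated by any test.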

How the results depend on the processing

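Tests with the strict marker gate and with the denominators that leave out only erythroid-like cells or only neutrophil-like cells were chosen only after the result was seen. No paired analysis was possible because there was 1 library per group, so nothing could be left out in turn. All values are log2 ratios, and the cause was not tested for any change. For MASH over Chow the B-like share, −0.29 as reported, was −0.22 with the stricter filter, −0.12 at resolution 0.5, −0.19 with own clustering, −0.15 with the gate, −0.16 with the strict gate and −0.24 without erythroid-like and neutrophil-like cells. The plasma-like share was −0.0885 of the B lineage. With own clustering the erythroid-like share was 1.63, and the CD4-like and follicular helper-like shares turned to 0.22 and −1.57. The type I interferon response list in B-like cells was 0.62 without abundant gene families in the total, 0.97 with an offset of 1 CPM, 0.50 as a mean over cells and 0.13 with clusters weighted alike. With clusters weighted alike, signs turned for the lists of B cell activation and antigen receptor response (−0.0189) and interferon-gamma response (−0.000741) in B-like, follicular helper (−0.10) in T-like and cell cycle (0.55) in neutrophil-like cells, and for Ifit3 (−0.35), Rgs13 (−0.00841) and Ifi47 (−0.0405) in B-like and Mki67 (0.63) in neutrophil-like cells. H1f5 in plasma-like cells turned to 0.13 without the smaller cluster, the only effect of that setting there and in NK-like cells. Signs also turned for the MYC and ribosome biogenesis list in B-like cells (−0.00168), Top2a in plasma-like cells (0.22) and Ctsl in monocyte- and macrophage-like cells (0.0345) as a mean over cells, for the myeloid suppressor and neutrophil activation list in dendritic-like cells (−0.0170) with no minimum of UMIs, and for the lipid-associated macrophage list in macrophage-like cells (−0.61) with the stricter cell filter. For Phe-free over MASH the B-like share, −0.16 as reported, was −0.22 with the stricter filter, −0.29 at resolution 0.5, −0.23 with own clustering, −0.23 with the gate, −0.22 with the strict gate and −0.0584 without erythroid-like and neutrophil-like cells. The plasma-like share was 0.17 with the gate. The erythroid-like share was −0.67 with the looser and −0.18 with the stricter filter. With own clustering the follicular-like share turned to 0.0888 and the germinal centre-like to −0.82. The same weighting turned signs for the germinal centre (−0.0590), B cell identity (0.00798) and cell cycle (−0.14) lists in B-like, regulatory T (−0.0193) in T-like, cell cycle in neutrophil-like (−0.17) cells, and for Top2a (−0.18) and Mki67 (−0.32) in B-like and Mki67 (−0.29) in neutrophil-like cells. Without the smaller NK-like cluster the cell cycle list turned to −0.14 there. The interferon list in B-like cells was −0.74 with an offset of 1 CPM. The stricter cell filter turned the mitochondrially encoded list in B-like cells (−0.00339) and Apoe in plasma-like cells (1.65). The unfolded protein response list in plasma-like cells turned to −0.0405 with TMM scaling, −0.0383 without abundant families and −0.0729 as a mean over cells, where the cell cycle list turned to −0.0915. Of 353 recomputed class and subset shares, 272 stayed within the reported interval, 77 moved outside it and 4 changed sign, where a change of sign was counted only for values whose reported interval excluded 0. These numbers were 666, 212 and 18 of 896 list medians, 640, 308 and 11 of 959 named genes, 8, 0 and 0 of 8 isotype shares, and 38, 34 and 0 of 72 shares of cells with a UMI. Where the reported interval included 0, a further 13 recomputed class and subset shares and 38 list medians lay on the other side of 0. The number of cells limits the isotype shares, since Igha led in only 5 of 262 MASH plasma-like cells and the ratio of its shares had an interval from 0.144 to 1.06, and depth limits the shares of cells with a UMI, of which 34 moved with the depth of thinning.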

Other observations

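The tests on pancreatic acinar genes and on heavy-chain variable segments were chosen only after the result was seen. In B-like cells of MASH over Chow, the B cell identity list had a median of 0.05 with 11 of 16 members higher, at percentile 74.0, and the B cell activation and antigen receptor response list 0.05 with 12 of 17 higher, at percentile 98.9. The glycolysis list was higher in 11 of 16 members with a median of 0.11 at percentile 99.97, and the immediate early and dissociation list in 12 of 17 with a median of 0.08 at percentile 99.7. The heat shock list was lower in 7 of 11 members with a median of −0.10 at percentile 0.63, and the mitochondrially encoded list in 10 of 13 with a median of −0.10 at percentile 1.06. The cytosolic ribosomal protein list was higher in 58 of 76 members with a median of 0.04, and the MYC and ribosome biogenesis list in 12 of 18 with a median of 0.04. Medians of the NF-kB and inflammatory cytokine, MHC class II presentation, cholesterol synthesis and uptake, fatty acid synthesis and oxidation, one-carbon and methionine metabolism, oxidative stress (NRF2), apoptosis and p53, and unfolded protein response lists were −0.03, 0.06, −0.03, −0.03, 0.00, 0.05, −0.06 and −0.02.

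In B-like cells of Phe-free over MASH, the cytosolic ribosomal protein list was higher in 65 of 77 members with a median of 0.07 at percentile 100. The cholesterol synthesis and uptake list was higher in 17 of 20 members with a median of 0.03 at percentile 96.5. The immediate early and dissociation list was lower in 11 of 17 with a median of −0.08 at percentile 0.43, and the B cell identity list in 9 of 16 with a median of −0.05 at percentile 8.87. Medians of the heat shock, mitochondrially encoded, glycolysis, oxidative phosphorylation (nuclear), MHC class II presentation and MYC and ribosome biogenesis lists were 0.03, 0.03, 0.02, 0.01, 0.04 and 0.00.

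A heavy-chain variable segment was assigned to 221 Chow, 186 MASH and 286 Phe-free plasma-like cells, which used 43, 44 and 46 segments. The segment used most was Ighv1-14 in Chow with 24 cells (10.9% [7.08–15.7]), Ighv6-3 in MASH with 14 cells (7.53% [4.18–12.3]) and Ighv2-9 in Phe-free with 31 cells (10.8% [7.48–15]). In B-like cells Ighv1-14 was used most in all 3 libraries, in 9.13%, 8.84% and 8.25% of assigned cells. A pair of plasma-like cells drawn at random used the same segment in 3.91%, 3.19% and 4.27% of draws.

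Transcripts of 16 pancreatic acinar genes stood at 217 CPM over all Chow barcodes, 30.7 CPM over MASH and 46.3 CPM over Phe-free barcodes, and had a UMI in 16.7%, 8.67% and 13% of barcodes. In B-like cells 15 of 15 measured acinar genes were lower in MASH than in Chow, with a median of −0.46. Cela1 went the other way, at 17.4, 20.1 and 32.0 CPM over all barcodes. It held 2408 of the 30044 acinar UMIs in Chow, 3070 of 4677 in MASH and 5117 of 7416 in Phe-free. It had a UMI in 6.57%, 7.23% and 11.2% of barcodes. The summed levels and barcode shares of MASH and Phe-free thus mostly reflect Cela1 and understate how much lower the other genes were.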
